A study of Mus musculus with 3 samples.

How the data were processed

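Transcripts of 135 individual mouse cells, grown for 5 days from single sorted HSCs, were measured in 3 libraries by a modified STRT-seq protocol, in which each cell carries a barcode and each transcript a random molecular identifier, per the labels' protocols. The submitters' processing notes name CASAVA 1.8, TopHat2 2.0.12, HTSeq and the mm10 genome, without the role of each. The deposited expression values are called TPM but were treated as CPM, since within a cell all values are whole multiples of 1 step shared by all genes, with no scaling by gene length. Multiplied by the deposited count of molecules per cell, 100% of the 960461 values above 0 came out whole within 0.02 molecules (largest distance 0.0073), and the recovered totals and gene numbers equalled the deposited counts in all 135 cells. The deposited mapping rate is a fraction of reads aligned, per the file headers. The files list 23154 genes, of which 13901 had a molecule. No 2 cells held identical values. Filters on cells and genes before deposit are not given in the sources used here.

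Treatment and well were read from the cell names as the file header defines them. Labels gave no animals. The replicate was the well, since each was founded by 1 HSC, and cells were not used as replicates in any comparison of the treatments. The binomial intervals and the reassignments of cells to wells in the closing section take cells as units. The design text states 7 or 8 cells per well, whereas TGF-β1 wells in the files held 3 to 13. Well P1w4 held 13 cells in 2 runs of barcodes, and P1w7 held cells in both mixed libraries. No cell had under 2000 genes and none was removed. No doublet caller was run, since cells were picked by hand.

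The mean CPM over the cells of a well was taken as log2(CPM + 10), so fold changes understate the change of genes with low levels. Genes with a mean over wells of at least 10 CPM were tested with limma 3.58.1 (trend, 2-sided, Benjamini-Hochberg adjustment) in R 4.3.3. The 23 gene lists were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation. With the estimate, 5 of the 8 lists that passed still passed: TGF-β and SMAD response, CDK inhibitors, glycolysis, interferon response and oxidative phosphorylation. The planned fry test of limma, which asks whether members changed and not whether they changed more than other genes, passed the same 8. Lists with under 3 tested members had no list test. Measures per cell were averaged per well and compared by exact permutation over all 43758 splits, in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Cells were clustered with scanpy 1.11.5 and leidenalg 0.10.2 on log2(CPM + 1) of the 2000 most variable genes, 15 principal components, 10 neighbours and a resolution of 0.8. Plots were drawn with matplotlib 3.10.9. Gene positions are from GENCODE M21 for mm10, 1-based, and all named genes are annotated as protein-coding.

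Genes were named by a rule: the 12 largest rises and the 12 largest falls among genes that passed with the same sign in both mixed libraries; from each list up to 6 passing members by smallest p and the 2 of highest mean; and Tgfb1, Tgfbr1, Tgfbr2, Smad7, Cdkn1c, Cdkn1a, Kit, Mpl, Procr and Mki67 in any case. The rule took 121 tested genes, and the text names 84 of them, chosen after their values were seen.

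The count test with edgeR 4.0.16 on recovered molecules, summed per well, called 1089 genes, and DESeq2 1.42.0 called 1376. Other alternatives set before the data were examined were pseudocounts of 1 and 50 CPM, no filter or one at 50 CPM, library as a block, the mixed libraries alone, each well left out, logarithms averaged over cells, median-ratio size factors, limma without trend, library and treatment as the unit, cells with at least 2000 genes, medians over cells, thinned cells for depth and marker shares, cell cycle shares without ribosomal protein genes, and cluster resolutions of 0.4 and 1.2 or centring within library. The tests, gene lists, naming rule and these alternatives were fixed before the data were examined. Chosen after seeing the data were 5 alternatives for the gene and list results: thinning to 50000 molecules, cells of 100000 to 400000 molecules, array weights, leaving out the 3 TGF-β1 wells of lowest mapping rate, and leaving out P1w4 as the well with 2 barcode runs. The last repeats the planned leave-out of P1w4, so the 36 settings count that fit under 2 names. The adjustment of marker shares over 8 lists was also set after the unadjusted values had been seen, when 3 of the 8 had an exact permutation p under 0.05.

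On simulated molecules at the real depths, with 200 genes changed, of which 67, 65 and 63 changed 1.5-fold, 2-fold and 4-fold were among the 6971 tested, the limma test recovered 19.4% of genes changed 1.5-fold, 66.2% of those changed 2-fold and 100% of those changed 4-fold, and called 4 of 6776 unchanged genes. These rates hold for the simulated molecules only. The data called 1519 of 7034 genes, far more than were changed in the simulation, so the rates may differ in the data. Intervals are exact binomial at 95% and cover counting error only.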

Results

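The study cultured mouse hematopoietic stem cells (HSCs), the bone marrow cells from which all blood lineages arise, and measured the transcripts of individual daughter cells by a 3' STRT-seq protocol with molecular identifiers. Each well was founded by 1 sorted HSC, and its progeny were picked by hand on day 5. Control wells held stem cell factor (SCF) and thrombopoietin (TPO), cytokines that keep HSCs alive and dividing; the other wells also held TGF-β1, a secreted growth inhibitor of these cells. There were 10 control wells with 79 cells and 8 TGF-β1 wells with 56 cells, in 3 sequencing libraries. Library TP24 held 39 control and 16 TGF-β1 cells, library TP25 held 16 and 40, and library TP26 held 24 control cells only. Control wells gave 7 to 8 cells each and TGF-β1 wells 3 to 13. The cells held 13868 to 660255 molecules under TGF-β1 and 15638 to 1461089 in control. All values below are means ± SD over wells, with n = 10 control and n = 8 TGF-β1 wells. Animals were not named for the wells, so the p-values measure the spread between wells, which may lie within a single animal.

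Cells grown with TGF-β1 yielded fewer molecules and fewer detected genes than control cells. Molecules per cell dropped from 609021 ± 112576 to 250669 ± 95710 (2-sided exact permutation p = 2.29e-05, the smallest that the 43758 splits of the wells can give, and adjusted p = 5.71e-05 over 5 measures of depth). Genes detected per cell dropped from 7888 ± 319 to 6073 ± 920 (exact permutation p = 2.29e-05), and on both measures all 8 TGF-β1 wells lay below the lowest control well. Within library TP24 the genes numbered 7809 ± 312 in 5 control and 5461 ± 959 in 3 TGF-β1 wells (exact p = 0.0179, the smallest that 56 splits allow). Within TP25 they numbered 8082 ± 395 in 2 and 6440 ± 678 in 6 wells (exact p = 0.0357, the smallest that 28 splits allow). After each cell was thinned to 50000 molecules, which left out 2 control and 7 TGF-β1 cells, genes per cell were 5306 ± 208 and 4691 ± 428 (exact permutation p = 4.34e-04). Aligned reads per cell were also lower, 2906692 ± 514674 against 1339430 ± 669183 (exact permutation p = 9.14e-05). Over all wells aligned reads per molecule did not differ beyond the spread, 4.77 ± 1.14 against 5.21 ± 1.46 (exact permutation p = 0.487). Within each mixed library they were lower under TGF-β1, though not beyond the spread. In TP24 they were 4.32 ± 0.568 and 4.09 ± 0.351 (exact permutation p = 0.589). In TP25 they were 6.71 ± 0.862 and 5.56 ± 1.56 (exact permutation p = 0.393). The share of reads aligned was 77.7 ± 1.12% and 74.5 ± 3.13% (exact permutation p = 0.00523).

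**Figure D1:**
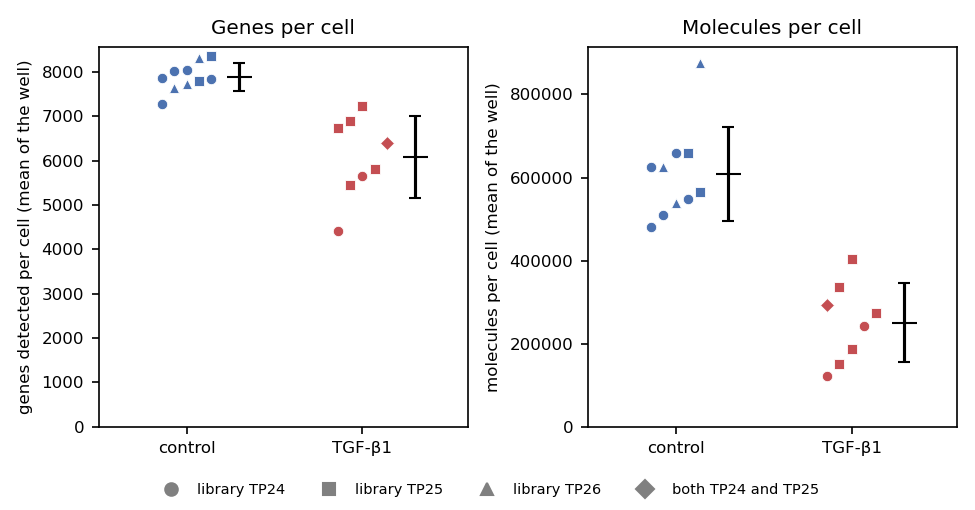
Genes detected and molecules per cell, as the mean of each well, for 10 control and 8 TGF-β1 wells; symbols mark the library, and the black bar and whiskers give the mean ± SD over wells. All 8 TGF-β1 wells lie below the lowest control well in both panels, with group means of 7888 and 6073 genes.

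The series' title poses the question of how TGF-β1 acts on dividing HSCs, and the central comparison was between TGF-β1 and control wells over all genes. As shares of a cell's molecules, transcripts of TGF-β targets and cell cycle inhibitors rose under TGF-β1. Those of glycolysis, oxidative phosphorylation and 3 interferon-responsive membrane proteins fell. CPM values are such shares and TGF-β1 cells held fewer molecules, so a rise in CPM need not be a rise in molecules per cell. On the tested scale of log2(CPM + 10), Chad, which encodes the matrix protein chondroadherin, rose most, from 4.13 ± 5.25 to 432 ± 239 CPM (log2 fold change 4.82, SE 0.28, adjusted p = 1.12e-12). Cd48, a surface receptor that stem cells lack and multipotent progenitors carry, fell most on that scale, from 326 ± 193 to 17.3 ± 11.3 CPM (log2 fold change -3.52, SE 0.29, adjusted p = 1.89e-09). By the ratio of group means, which has no pseudocount, other genes changed more, among them Itgae and Hes1 upward and Lmo1 downward. Of 7034 genes tested with limma, 1519 passed an adjusted p of 0.05, with 646 higher and 873 lower, and 2369 had an unadjusted p under 0.05. The direction in both mixed libraries matched that of the pooled comparison for 96.9% of the 1519 genes, against 49.95% of the genes that did not pass. The pooled comparison drew on the same wells, so selection largely sets both shares and they are no independent support. In 150 tested genes the wells of both groups did not overlap, which chance gives for 0.00457% of genes. With library as a block 993 genes passed, and without the control-only library 924. The share of called genes that were higher was 42.5% here, 55.9% with edgeR, 57.1% with DESeq2 and 18.2% with logarithms averaged over cells, a setting under which the median of all genes moved from -0.01 to -0.21 on the log2 scale.

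Among the genes with the largest rises were regulators of G protein signalling, a Notch-responsive repressor and a growth factor. Rgs2 (chromosome 1, 143999338 to 144004161), Rgs10 and Rgs1, which shorten G protein signals, rose from 41.3 ± 17.7 to 482 ± 327 CPM, from 5.38 ± 4.32 to 104 ± 51.3 CPM and from 9.77 ± 9.12 to 145 ± 144 CPM. Their log2 fold changes were 3.12, 2.82 and 2.60. Hes1, a transcriptional repressor downstream of Notch, rose from 0.547 ± 0.839 to 86.3 ± 56.2 CPM (log2 fold change 2.85, adjusted p = 7.91e-07). Fgf3, a fibroblast growth factor, rose from 10.5 ± 15.9 to 192 ± 119.6 CPM (log2 fold change 3.22, adjusted p = 2.04e-06). Tmem119, Smim5, Itm2a and Plac8 also rose, with log2 fold changes of 2.94, 2.73, 2.60 and 2.79. Plac8 varied widely between TGF-β1 wells, at 872 ± 1168 CPM, and 5 of 8 wells lay above the highest control well. P1w9 and P1w8, held in TP24 alone, were highest at 3440 and 1564 CPM. P1w7, with cells in both mixed libraries, was lowest at 33.6 CPM. P1w7 was also the lowest TGF-β1 well for Chad (115 CPM), Fgf3, Rgs2, Tmem119, Hes1, Rgs10, Smim5 and Ldlrad4. For Itm2a, Rgs1 and Pmepa1 another TGF-β1 well was lowest. Its Fgf3 level, 18.2 CPM, lay under that of control well P2wJ, 49.7 CPM. In control cells Chad (chromosome 11, 94565047 to 94569127 in mm10) was at 5.90 CPM in the wells of the mixed libraries and listed at 0 in the control-only library.

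The largest falls included genes of the cell surface, of mitochondria and of transcription. Lgals1 (chromosome 15, 78926725 to 78930465), which encodes the sugar-binding protein galectin-1, fell from 749 ± 546 to 84.3 ± 24.3 CPM (log2 fold change -2.70, adjusted p = 5.06e-07). Cd53, a tetraspanin of blood cells, fell from 70.3 ± 51.4 to 6.62 ± 3.18 CPM (log2 fold change -2.04, adjusted p = 2.04e-05). Lmo1, a LIM-domain transcriptional cofactor, fell from 50.7 ± 12.002 to 2.63 ± 1.57 CPM (log2 fold change -2.25, adjusted p = 3.06e-09). Chchd10, a protein of the mitochondrial intermembrane space, fell from 193 ± 44.9 to 48.3 ± 50.6 CPM (log2 fold change -2.28, adjusted p = 2.60e-05). Cfp, which encodes the complement factor properdin, and Gem, a small GTPase, had log2 fold changes of -2.18 and -2.10. Afp, Guca1a, Dkkl1, Rangrf and 1500009L16Rik fell with log2 fold changes between -2.06 and -1.99. Cd48 lies on chromosome 1, 171682009 to 171705258, and in all 8 TGF-β1 wells it was below the lowest control well.

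**Figure D2:**
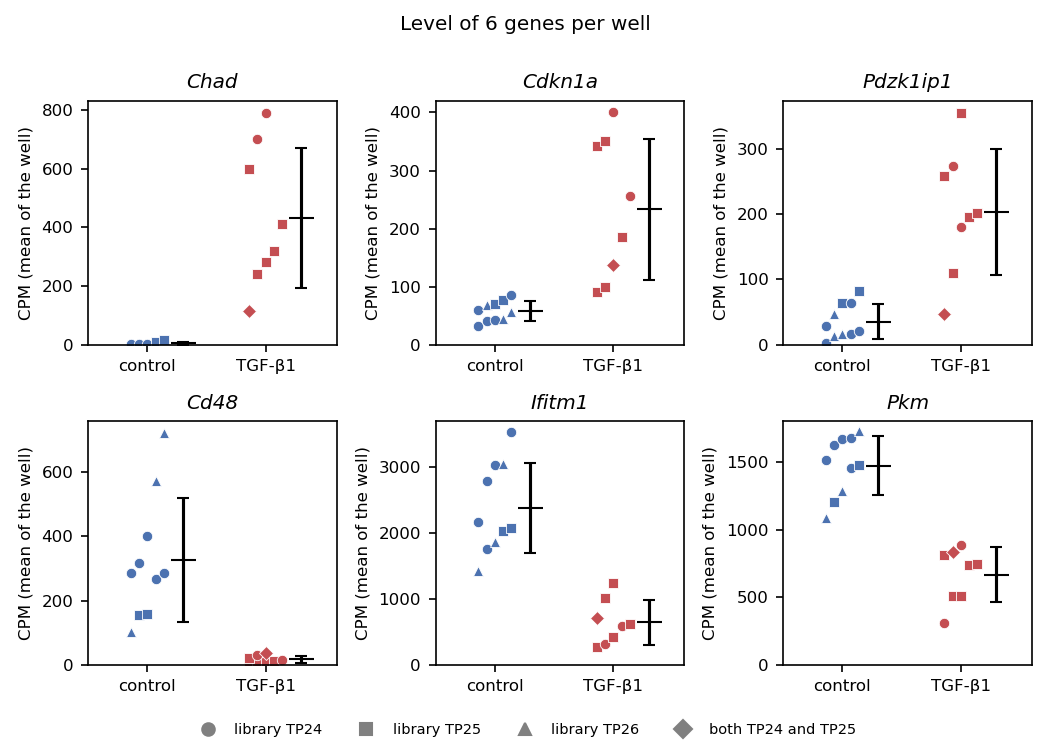
Level of 6 genes in CPM, as the mean of each well's cells, in 10 control and 8 TGF-β1 wells, with the mean ± SD over wells in black and the library as the symbol. Chad, Cdkn1a and Pdzk1ip1 lie higher and Cd48, Ifitm1 and Pkm lower under TGF-β1, with Chad at means of 4.13 and 432 CPM.

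Genes of the TGF-β and SMAD response rose. In this list 8 of the 15 tested members rose, 1 fell and 6 did not pass, and the counts adjusted over the list alone were 10 higher and 1 lower (camera adjusted p = 2.25e-06; adjusted p = 0.0311 with an estimated correlation). Ldlrad4 and Pmepa1, membrane proteins that restrain SMAD activation, rose. Ldlrad4 went from 3.004 ± 3.61 to 84.9 ± 43.1 CPM (log2 fold change 2.69, adjusted p = 2.98e-07) and Pmepa1 from 0.397 ± 0.645 to 61.0 ± 36.7 CPM (log2 fold change 2.62, adjusted p = 8.30e-09). Skil, a SMAD corepressor, rose from 1.26 ± 1.42 to 53.1 ± 25.3 CPM (log2 fold change 2.39, adjusted p = 2.03e-08). Smad7 (chromosome 18, 75367529 to 75395935), the inhibitory SMAD, rose from 1.196 ± 0.916 to 23.3 ± 23.6 CPM (log2 fold change 1.26, adjusted p = 0.00277). Itgae, an integrin chain induced by TGF-β in lymphocytes, and Klf10 rose with log2 fold changes of 1.70 and 1.003. Id1, a target of bone morphogenetic proteins that TGF-β represses in many cells, fell from 137 ± 69.2 to 35.8 ± 29.5 CPM (log2 fold change -1.81, adjusted p = 2.18e-04). The receptor gene Tgfbr1 rose from 21.3 ± 8.97 to 51.4 ± 45.1 CPM (log2 fold change 0.79, adjusted p = 0.0388), a call that ended in 15 of the 35 other settings in which it was tested. Tgfbr2 did not pass, at 6.30 ± 6.34 and 17.1 ± 19.8 CPM (adjusted p = 0.197). Tgfb1 itself, at 3.397 ± 2.51 and 2.34 ± 1.67 CPM, lay under the filter of 10 CPM and was not tested. With a filter at 50 CPM, which leaves fewer members, the list did not pass.

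Inhibitors of cyclin-dependent kinases rose as well. Of the 7 listed, 3 reached the filter and all 3 rose, also when adjusted over the list alone (camera adjusted p = 9.69e-04; adjusted p = 0.0372 with an estimated correlation). Cdkn1a (chromosome 17, 29090976 to 29100727), which encodes p21, rose from 57.6 ± 17.6 to 233 ± 122 CPM (log2 fold change 1.71, adjusted p = 1.29e-05). Cdkn2d (p19) rose from 59.5 ± 14.6 to 143 ± 57.7 CPM (log2 fold change 1.09, adjusted p = 1.67e-04). Cdkn1c (p57) rose from 1.13 ± 1.52 to 31.5 ± 47.0 CPM (log2 fold change 1.16, adjusted p = 0.0363). The Cdkn1c call ended in 15 of its 34 other settings, its log2 fold change was 2.26 in TP24 and 0.41 in TP25, and 4 of the 8 TGF-β1 wells lay above the highest control well. In the list of quiescence and anti-proliferative genes, 5 of the 6 tested members rose, 0 fell and 1 did not pass, and the counts adjusted over the list alone were 6 higher and 0 lower (camera adjusted p = 5.16e-04; adjusted p = 0.117 with an estimated correlation). Txnip, an inhibitor of thioredoxin and glucose uptake, rose from 78.2 ± 19.2 to 193 ± 72.7 CPM (log2 fold change 1.14, adjusted p = 1.30e-04). The anti-proliferative genes Btg1 and Btg2 also rose. Btg1 went from 6.88 ± 3.96 to 32.8 ± 31.4 CPM (log2 fold change 1.08, adjusted p = 0.0108) and Btg2 from 5.54 ± 3.74 to 26.4 ± 19.7 CPM (log2 fold change 1.05, adjusted p = 0.00986). The Btg1 call ended in 2 of its 34 other settings, library as a block among them. The Btg2 call ended in 3 of its 35 other settings, with a log2 fold change of 0.19 in cells of 100000 to 400000 molecules.

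Neither list of cell cycle genes passed as a whole with all wells, and without P1w2 the G2/M list passed as lower (camera adjusted p = 0.0359). The share of each cell's molecules from G1/S and replication genes went from 0.486 ± 0.0612% to 0.494 ± 0.118% (exact permutation p = 0.853; adjusted p = 0.853 over both lists), and that from G2/M and mitosis genes from 1.17 ± 0.210% to 1.13 ± 0.405% (exact permutation p = 0.790; adjusted p = 0.853). Within library TP24 the exact permutation p was 0.357 for G1/S and 0.0893 for G2/M, and within TP25 0.786 and 0.964. Leaving out P1w3, P1w4, P1w5, P2wA or P2wH turned the sign of the G1/S difference, and leaving out P1w6 or P1w9 that of G2/M, all with values near 0. In the G1/S list 1 of the 41 tested members rose, 3 fell and 37 did not pass, and the counts adjusted over the list alone were 1 higher and 3 lower (camera adjusted p = 0.505), and in the G2/M list 3 of the 53 tested members rose, 8 fell and 42 did not pass, and the counts adjusted over the list alone were 3 higher and 8 lower (camera adjusted p = 0.434). Members moved apart. Rfc2, a subunit of the clamp loader, rose from 295 ± 49.8 to 616 ± 132 CPM (log2 fold change 1.02, adjusted p = 5.04e-06). Mki67, the proliferation antigen Ki-67, rose from 79.3 ± 23.8 to 199 ± 149 CPM (log2 fold change 1.001, adjusted p = 0.00634). That call ended in 2 of 36 other settings, with library as a block and with logarithms averaged over cells. Cdk1, the mitotic kinase, fell from 465 ± 92.4 to 289.5 ± 82.2 CPM (log2 fold change -0.71, adjusted p = 0.00214). Ube2c and Cdc20, genes of the mitotic ubiquitin pathway, fell with log2 fold changes of -0.87 and -0.95. Exo1 and Gins2 fell by 0.75 and 0.71 on the log2 scale, calls that ended in 6 and 7 other settings.

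Genes of HSC identity moved in both directions. In the HSC list 3 of the 14 tested members rose, 4 fell and 7 did not pass, and the counts adjusted over the list alone were 4 higher and 5 lower (camera adjusted p = 0.948); its median log2 fold change was -0.03 and its mean 0.05, so the signs differ. The list's share of a cell's molecules, which its abundant members dominate, went from 0.0688 ± 0.0198% to 0.128 ± 0.0323% (exact permutation p = 6.86e-05; adjusted p = 2.51e-04 over 22 lists). For this share the exact permutation p was 0.0179 within TP24 and 0.214 within TP25. Pdzk1ip1, a membrane protein enriched in HSCs, rose from 35.5 ± 26.8 to 203 ± 96.5 CPM (log2 fold change 2.29, adjusted p = 2.02e-05). Ly6a (Sca-1) rose from 156 ± 92.7 to 544 ± 387 CPM (log2 fold change 1.64, adjusted p = 0.00131). The transcription factor Gata2 rose from 34.6 ± 14.1 to 135 ± 120.4 CPM (log2 fold change 1.37, adjusted p = 0.00417), a call that ended in 2 of 36 other settings, library as a block among them. Esam, an endothelial and HSC adhesion molecule, fell from 48.6 ± 34.6 to 12.3 ± 9.63 CPM (log2 fold change -1.26, adjusted p = 0.00427). Procr, the endothelial protein C receptor, fell from 23.8 ± 18.04 to 4.15 ± 3.03 CPM (log2 fold change -1.08, adjusted p = 0.00859). The transcription factors Hlf and Mycn had log2 fold changes of -1.11 and -1.24. The receptors for the cytokines of the medium did not pass: Kit was at 47.3 ± 19.0 and 63.1 ± 48.2 CPM, and Mpl at 47.7 ± 19.4 and 29.3 ± 18.4 CPM. Mpl passed as lower in 3 of its 35 other settings. Of the multipotent and lymphoid progenitor list only Cd48 and Cd34 reached the filter, and both passed, also when adjusted over the list alone. Cd34, a sialomucin of progenitors, rose from 218 ± 90.7 to 418 ± 118 CPM (log2 fold change 0.96, adjusted p = 0.00104).

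Megakaryocyte genes were higher as a list in camera with the preset correlation but not with an estimated one, and of the granulocyte genes more fell than rose. In the megakaryocyte list 6 of the 10 tested members rose, 0 fell and 4 did not pass, and the counts adjusted over the list alone were 7 higher and 2 lower (camera adjusted p = 0.00479; adjusted p = 0.191 with an estimated correlation). Cd9, a tetraspanin of platelets, rose from 386 ± 87.2 to 951 ± 392 CPM (log2 fold change 1.16, adjusted p = 3.58e-04). Plek (pleckstrin) rose from 10.7 ± 6.13 to 60.3 ± 39.5 CPM (log2 fold change 1.53, adjusted p = 8.82e-04). Itga2b, the platelet integrin chain CD41, rose from 40.1 ± 30.1 to 133 ± 118 CPM (log2 fold change 1.25, adjusted p = 0.0194), a call that ended in 7 of 36 other settings. Pf4 did not pass (adjusted p = 0.103), though it passed as lower in 4 of 36 other settings. In the erythroid list 1 of the 3 tested members rose, 0 fell and 2 did not pass, and the counts adjusted over the list alone were 1 higher and 0 lower (camera adjusted p = 0.323). The list's share of molecules went from 0.0477 ± 0.0118% to 0.101 ± 0.0507% (exact permutation p = 4.57e-04; adjusted p = 0.00126 over 22 lists). For this share the exact permutation p was 0.0357 within TP24 and 0.464 within TP25. Car2, a carbonic anhydrase, rose from 313 ± 102 to 798 ± 444 CPM (log2 fold change 1.22, adjusted p = 3.49e-04) and accounts for most of the change in that share. In the granulocyte and monocyte list 1 of the 8 tested members rose, 2 fell and 5 did not pass, and the counts adjusted over the list alone were 1 higher and 2 lower (camera adjusted p = 0.134). That list passed as lower with edgeR (adjusted p = 0.0446), with DESeq2 (0.00736), with cells of 100000 to 400000 molecules (0.009001) and without P1w8 (0.0355). Its members Mpo, Elane and Ctsg reached the filter through the control-only library. They were at 216, 131 and 78.8 CPM there, against 0.0238, 0.134 and 2.20 CPM in the other control wells. How far these genes carried the calls was not tested. Prtn3, a granule protease, fell from 312 ± 84.4 to 109 ± 45.2 CPM (log2 fold change -1.50, adjusted p = 6.52e-06). Lyz2, lysozyme, fell from 182 ± 121 to 70.3 ± 60.6 CPM (log2 fold change -1.54, adjusted p = 0.00352). The myeloid transcription factor Spi1 rose from 203 ± 47.5 to 379.9 ± 223 CPM (log2 fold change 0.72, adjusted p = 0.0207), a call that ended in 9 of 36 other settings. Mpo, a granule peroxidase singled out after its values were seen, was found in all 24 cells of the control-only library, at 109 to 332 CPM, against 1 of the 55 other control cells and 1 of the 56 TGF-β1 cells. Prtn3 stood at 377 CPM in the control-only library and 284 CPM in the other control wells. Of the mast cell, macrophage and stroma lists, 2, 1 and 1 members reached the filter, too few for a list test, and none passed over all genes.

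Transcripts of energy metabolism fell. Of 73 tested genes for nuclear-encoded subunits of oxidative phosphorylation, 53 fell, 1 rose and 19 did not pass, and adjusted over the list alone 57 were lower and 2 higher (camera adjusted p = 5.25e-19; adjusted p = 0.0372 with an estimated correlation). Their share of a cell's molecules fell from 5.24 ± 0.294% to 3.99 ± 0.409% (exact permutation p = 2.29e-05, the smallest possible; adjusted p = 1.01e-04 over 22 lists). Cox7b of complex IV, Ndufc1 of complex I and Atp5c1 of the ATP synthase fell. Cox7b went from 1049 ± 85.5 to 657 ± 91.5 CPM (log2 fold change -0.68, adjusted p = 5.24e-06) and Ndufc1 from 583 ± 84.1 to 313 ± 66.5 CPM (log2 fold change -0.89, adjusted p = 6.23e-06). Atp5c1 went from 829 ± 43.4 to 566 ± 47.7 CPM (log2 fold change -0.55, adjusted p = 2.48e-05). Cox4i2, a hypoxia-inducible complex IV subunit, had a log2 fold change of -1.79. In glycolysis 0 of the 14 tested members rose, 9 fell and 5 did not pass, and the counts adjusted over the list alone were 0 higher and 10 lower (camera adjusted p = 1.61e-06; adjusted p = 0.0414 with an estimated correlation). Pkm (chromosome 9, 59656368 to 59679375), pyruvate kinase, fell from 1475 ± 219 to 669 ± 202 CPM (log2 fold change -1.18, adjusted p = 1.98e-06). Hk2, Ldha and Gapdh had log2 fold changes of -1.49, -0.71 and -0.64.

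Ribosome biogenesis genes were lower as a list, and the genes of ribosomal proteins did not pass as a list. In ribosome biogenesis and Myc targets 0 of the 21 tested members rose, 11 fell and 10 did not pass, and the counts adjusted over the list alone were 0 higher and 12 lower (camera adjusted p = 5.77e-06; adjusted p = 0.161 with an estimated correlation). Npm1, a nucleolar chaperone, fell from 2328 ± 221 to 1685 ± 352 CPM (log2 fold change -0.48, adjusted p = 5.56e-04). Srm, spermidine synthase, fell from 352 ± 80.0 to 151 ± 113 CPM (log2 fold change -1.49, adjusted p = 5.40e-04). Nop16 had a log2 fold change of -0.97. In the list of ribosomal proteins 16 of the 78 tested members rose, 5 fell and 57 did not pass, and the counts adjusted over the list alone were 18 higher and 5 lower (camera adjusted p = 0.0567; adjusted p = 0.843 with an estimated correlation). Rpl32 and Rps19 rose with log2 fold changes of 0.42 and 0.42. The list, with a median log2 fold change of 0.03, passed in 17 of the 36 other settings, 1 of which was counted under 2 names. Its share of molecules was 20.5 ± 1.16% in 5 control and 24.3 ± 0.867% in 3 TGF-β1 wells of TP24 (exact permutation p = 0.0179, the smallest that 56 splits allow), and 20.5 ± 0.131% and 20.8 ± 1.32% in 2 and 6 wells of TP25 (exact permutation p = 0.750). Over all wells it was 20.4 ± 0.921% and 21.8 ± 2.19% (exact permutation p = 0.0856).

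Of 12 listed interferon-responsive genes only 4 reached the filter. All 4 passed, 3 lower and 1 higher, also when adjusted over the list alone (camera adjusted p = 0.00191; adjusted p = 0.0414 with an estimated correlation). Ifitm1 (chromosome 7, 140967221 to 140969825) and Ifitm3, membrane proteins that block viral entry, fell. Ifitm1 went from 2369.8 ± 681 to 648 ± 340.0 CPM (log2 fold change -1.97, adjusted p = 3.08e-07) and Ifitm3 from 1722 ± 385 to 516 ± 238 CPM (log2 fold change -1.85, adjusted p = 5.93e-07). Bst2, tetherin, fell from 139 ± 41.8 to 52.1 ± 16.9 CPM (log2 fold change -1.26, adjusted p = 3.88e-05). Stat1, the transcription factor of the pathway, rose from 15.04 ± 4.63 to 38.1 ± 30.5 CPM (log2 fold change 0.75, adjusted p = 0.0448), a call that ended in 24 of its 35 other settings. Without the filter on low values the list did not pass (camera adjusted p = 0.0905), and its median log2 fold change was -0.02. In SCF and TPO feedback 0 of the 5 tested members rose, 1 fell and 4 did not pass, and the counts adjusted over the list alone were 0 higher and 2 lower (camera adjusted p = 0.504). Its share of molecules went from 0.0345 ± 0.00727% to 0.0218 ± 0.00658% (exact permutation p = 0.0027; adjusted p = 0.00593 over 22 lists). For this share the exact permutation p was 0.0179 within TP24 and 0.107 within TP25. Socs2, an inhibitor of cytokine signalling, fell from 175 ± 70.4 to 50.7 ± 24.7 CPM (log2 fold change -1.60, adjusted p = 2.41e-05) and accounts for most of the change in that share. The list's median, 0.06, and mean, -0.30, differ in sign. In p53 and apoptosis 2 of the 5 tested members rose, 1 fell and 2 did not pass, and the counts adjusted over the list alone were 2 higher and 1 lower (camera adjusted p = 0.323). Its share of molecules went from 0.0487 ± 0.0105% to 0.0691 ± 0.0218% (exact permutation p = 0.019; adjusted p = 0.038 over 22 lists). Cdkn1a, given above with the CDK inhibitors, is also a member here and accounts for most of that change. For the p53 share the exact permutation p was 0.696 within TP24 and 0.0714 within TP25. Ccng1, cyclin G1, rose from 31.7 ± 10.2 to 98.4 ± 39.4 CPM (log2 fold change 1.30, adjusted p = 2.23e-04). The nuclease gene Aen fell from 59.2 ± 14.3 to 28.0 ± 11.2 CPM (log2 fold change -0.90, adjusted p = 0.00213). In cytoskeleton and adhesion 2 of the 15 tested members rose, 2 fell and 11 did not pass, and the counts adjusted over the list alone were 4 higher and 2 lower (camera adjusted p = 0.673). The test's direction was up while median and mean, -0.01 and -0.02, lay below 0. Cd44, the hyaluronan receptor, rose from 24.5 ± 6.70 to 155 ± 72.3 CPM (log2 fold change 2.12, adjusted p = 7.78e-07). Zyx, zyxin, had a log2 fold change of 1.11. None of the 4 tested immediate early and stress genes passed (camera adjusted p = 0.771), and no mitochondrially encoded gene was listed. With library as a block Btg1, Mki67, Gins2, Gata2, Itga2b, Spi1 and Stat1 no longer passed. Their directions stayed, with log2 fold changes of 1.04, 0.85, -0.64, 0.95, 1.19, 0.72 and 0.64.

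**Figure D3:**
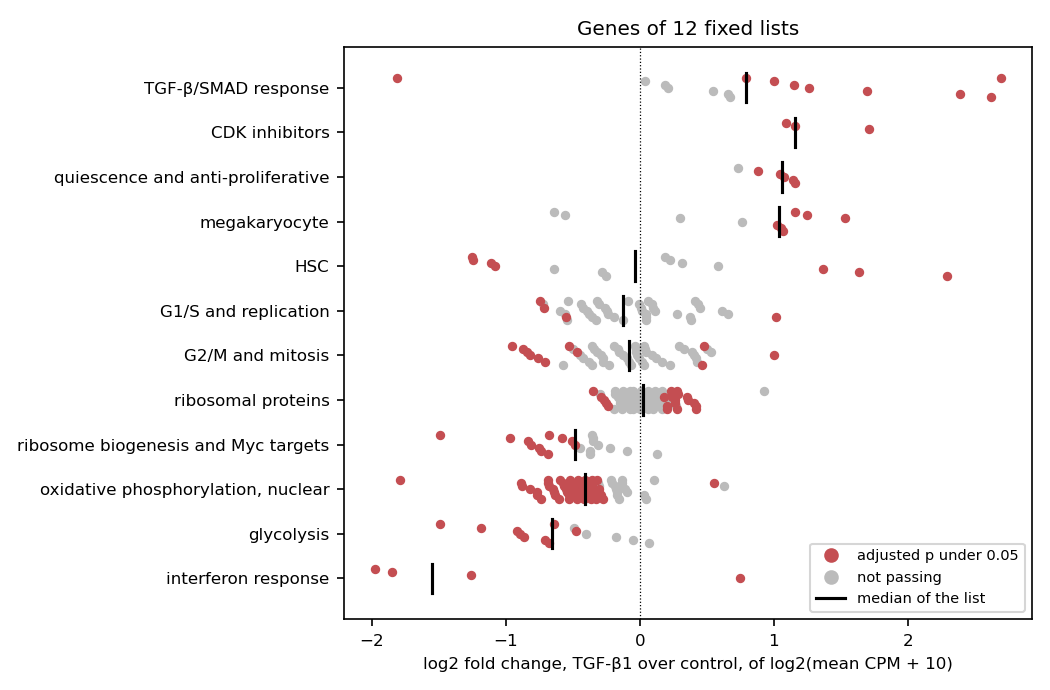
Log2 fold change of TGF-β1 over control, on the scale of log2(mean CPM + 10), for every tested gene of 12 lists; red points passed an adjusted p of 0.05, grey points did not, and black bars mark the list medians. Most points of oxidative phosphorylation and glycolysis lie left of 0, with medians of -0.41 and -0.66, and those of the CDK inhibitors lie right of 0.

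Markers of 5 lineages were present in all cells. At least 1 molecule of the HSC, progenitor, megakaryocyte, erythroid and granulocyte lists was found in 79 of 79 control cells (exact 95% binomial interval 95.4 to 100%) and in 56 of 56 TGF-β1 cells. A macrophage or dendritic cell marker was present in 97.5 ± 5.27% of a control well's cells and 66.7 ± 19.2% under TGF-β1 (exact permutation p = 2.97e-04; adjusted p = 0.00238 over 8 lists). The shares were 78.4 ± 17.8 and 52.7 ± 24.1% for mast cell markers (exact permutation p = 0.0141; adjusted p = 0.0563) and 96.3 ± 6.04 and 81.5 ± 20.9% for stromal markers (exact permutation p = 0.0328; adjusted p = 0.0875). The first 5 shares were at their ceiling and could not show a difference. In cells thinned to 50000 molecules, the number of progenitor markers per cell was 2.26 ± 0.205 and 1.73 ± 0.359 (exact permutation p = 0.00128) and that of HSC markers 9.78 ± 1.46 and 8.04 ± 1.41 (exact permutation p = 0.0212). Erythroid markers numbered 2.99 ± 0.407 and 2.53 ± 0.427 (exact permutation p = 0.0293) and macrophage markers 0.816 ± 0.224 and 0.529 ± 0.3003 (exact permutation p = 0.0325). Megakaryocyte markers went the other way, 6.84 ± 1.11 and 7.47 ± 1.40 (exact permutation p = 0.293), and the granulocyte, mast cell and stromal numbers had exact permutation p = 0.122, 0.225 and 0.292. These p-values were not adjusted over the 8 lists. Before thinning, the erythroid marker Car1 was found in 23 of the 24 cells of the control-only library. It was found in 0 of the 55 other control cells and 0 of the 56 TGF-β1 cells. How far Car1 raised the erythroid number of control cells was not tested. Shares of cells follow depth, and the median cell held 631804 molecules in control and 195318.5 under TGF-β1. With cells thinned to 50000 molecules the macrophage shares were 72.5 ± 18.2 and 48.3 ± 31.2% (exact permutation p = 0.0559), the mast cell shares 48.9 ± 37.7 and 43.2 ± 24.9% (exact permutation p = 0.716) and the stromal shares 71.3 ± 22.6 and 61.5 ± 24.7% (exact permutation p = 0.392).

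Control cells held similar numbers of molecules and genes in the 3 libraries, though TP25 was sequenced more deeply. Unsupervised clustering followed library and treatment. Control cells held medians of 634114, 555500 and 640412 molecules and 8043, 8330 and 8032.5 genes in TP24, TP25 and TP26. Their mean aligned reads were 2598945, 3658788 and 2900744, and their median aligned reads per molecule 4.52, 6.70 and 4.23. Clustering gave 6 clusters, of which 4 held cells of 1 treatment only, and 22 of the 24 control cells of the control-only library formed a cluster of their own. Of the TGF-β1 cells, 27 formed a cluster drawn from TP25 alone, and 25 formed a cluster with 5 control cells. That cluster held a median of 137892 molecules per cell. After values were centred within library, there were 5 clusters, each with cells of both treatments, but unevenly: 1 held 28 control cells and 1 TGF-β1 cell and another 14 and 2. Since the treatments were spread unevenly over the libraries, centring also removed part of the treatment difference. The mixing therefore does not separate library from treatment. The clusters were left unnamed and their sizes were not tested.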

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

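All 8 values below were singled out because 1 well lay far from the others of its group by Dixon's criterion, among 192 groups of wells tested, of which chance singles out about 1 in 20. Of the tests below, the thinned cells, the cells of 100000 to 400000 molecules and the ratio of fold changes with and without the library block were chosen after the data were seen, the bounds for the thinned cells being written before that test was run.

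1500009L16Rik was at 4.71 CPM in control well P2wA, against 57.4 to 126 in the other control wells. Tgfbr2 was at 22.2 CPM in control well P2wC, against 0.501 to 8.90. Lyz2 was at 512 CPM in control well P2wH, against 107 to 202. In TGF-β1 well P1w7, Rfc2 was at 331 CPM, against 575 to 769.998, and Ccng1 at 24.6 CPM, against 76.4 to 145. Control well P2wC held 876569 molecules per cell, against 480483 to 660231. HSC genes made up 0.201% of molecules in TGF-β1 well P1w3, against 0.0970 to 0.137%, and megakaryocyte genes 0.220% in control well P2wJ, against 0.0859 to 0.145%.

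The 1519 genes that differed between the treatments were weighed against chance, depth and library. Of 100 splits of the 18 wells, only 1, the real one, called as many, and the highest other split called 1. With cells thinned to 50000 molecules 68.9% of the called genes were called again in the same direction, above the bound of 66%. Thinning leaves a cell's expected CPM as it was. That value therefore argues only against uneven counting of molecules as the whole cause and cannot test lower capture. The shift predicted from depth among cells of the same control well was 0.0499 of the observed fold change (median, with a bootstrap interval of 0.0205 to 0.0651). This argues against a shift with depth, of the kind seen within control wells, as the whole cause. With only the 24 control and 32 TGF-β1 cells of 100000 to 400000 molecules, 34.1% were called again, and whether depth or the loss of cells lowered that share was not tested. Control cells stayed the deeper ones in that window, with medians of 282480.5 molecules in control and 205880 under TGF-β1. With library as a block 61.2% were called again, which lay between the bounds of 50 and 66% written beforehand and left the matter undecided; the ratio of fold changes with and without the block, added afterwards, had a median of 0.985 with standard errors 1.1999 times as large, so effects kept their size while precision dropped. An action of TGF-β1 stays a candidate explanation for the rest, but RNA content, which may itself fall with treatment, cannot be separated from capture, since the treated cells were the shallower ones in both mixed libraries.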

How the results depend on the processing

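Alternatives chosen after the data were seen were thinning for genes and lists, the window of 100000 to 400000 molecules, array weights, and leaving out P1w4 or the 3 wells of lowest mapping rate. The 1519 called genes became 993 with library as a replicate block, 924 without the control-only library, 979 with library and treatment as the unit, 559 with cells of 100000 to 400000 molecules (24 control and 32 TGF-β1 cells) and 979 without the 3 TGF-β1 wells of lowest mapping rate; these settings use fewer wells, cells or degrees of freedom. The other settings stayed within 1.5 times, and no gene among the 1519 was called in the opposite direction under any of them. Leaving out each well in turn gave 1309 to 1726 genes, with at least 83.5% of the calls shared. Lists passing numbered 6 to 10 against 8, and 8 to 10 with each well left out. Under the block 9 lists passed, the added one being that of ribosomal proteins.

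Among the 36 settings leaving out P1w4 counts under 2 names, and the minimum of 2000 genes removed no cell. Of 80 named genes that passed, 59 passed in every setting in which they were tested, and 5 of 8 lists did. Among 2991 gene values under other settings 106 lost the call, 7 gained it and no called gene turned; among 642 list values 5 lost it, 24 gained it and no called list turned. The TGF-β and SMAD list lost its call with a filter at 50 CPM, the megakaryocyte list without filter, at 100000 to 400000 molecules and without the wells of lowest mapping rate, and the interferon list without filter. Of the 24 calls gained, 17 were of ribosomal proteins. The granulocyte list gained 4, with edgeR, with DESeq2, at 100000 to 400000 molecules and without P1w8. It holds Mpo, Elane and Ctsg, which were high in the control-only library. The G2/M list gained 1 without P1w2, and the HSC and p53 lists 1 each with a filter at 50 CPM.

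The macrophage share difference of -30.8 percentage points missed the adjusted threshold as a median over cells (-18.8) and with thinned cells (-24.2), where depth no longer differs. With each well left out it ranged from -35.6 to -26.6, the mast cell difference from -30.1 to -18.2 and the stromal difference from -17.4 to -8.45. The mast cell difference passed without P1w3, P1w5, P2wA, P2wF or P2wI (adjusted p = 0.0167 at the least, up to 0.106 over all wells left out) and the stromal one without P1w3, P1w5 or P1w7 (0.0306 to 0.257). Without the control-only library the mast cell difference shrank to -16.4 percentage points and did not pass (adjusted exact permutation p = 0.2996). The shares of the 5 other lists were 100% in both groups and could not show a difference. The G1/S difference ranged from -0.0191 to 0.0295 percentage points and that of G2/M from -0.155 to 0.0257; the cause was not tested. Genes per cell differed by -1979.5 to -1579 and molecules by -380176 to -328625. Clusters numbered 6, and 3 at a resolution of 0.4, as that setting merges clusters. Shallow TGF-β1 cells limit what can be seen: 7 held under 50000 molecules.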

Other observations

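Beyond the fixed lists, 16 gene families were chosen after the results for single genes had been seen, so their tests are not independent of those. The regulators of G protein signalling moved as a family: all 6 tested members rose, with a median log2 fold change of 1.93 (camera adjusted p = 2.14e-08; adjusted p = 0.00395 with an estimated correlation), though Rgs2, Rgs10 and Rgs1 had led to its choice. Of 77 mitochondrial ribosomal protein genes 43 fell and none rose (camera adjusted p = 3.03e-12; adjusted p = 0.0399 with an estimated correlation), as did 13 of 22 mitochondrial import genes (camera adjusted p = 9.55e-08; 0.0399 with an estimated correlation). Members also fell, with none rising, in the proteasome (15 of 43), the tricarboxylic acid cycle (7 of 16), nucleotide synthesis (7 of 18), spliceosomal ribonucleoproteins (7 of 10) and the chaperonin (6 of 8), whose calls ended with an estimated correlation (adjusted p = 0.111, 0.0518, 0.166, 0.165 and 0.165). Tubulins and translation initiation factors passed with the preset correlation (camera adjusted p = 0.0275 and 0.0351). Both calls ended with an estimated correlation (adjusted p = 0.370 and 0.287) and with library as a block (adjusted p = 0.0532 and 0.0501). Histones, MHC class I, tetraspanins, cathepsins, the vacuolar ATPase and cholesterol synthesis did not pass (camera adjusted p = 0.780, 0.763, 0.741, 0.465, 0.230 and 0.392).

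Tests chosen or altered only after the result was seen were those of transcripts crossing between barcodes, of P1w7 (the share of reassignments) and of P1w4 (the correlations within its runs). Mpo, Elane and Prg2, transcripts of neutrophil and eosinophil granules singled out after their values were seen, stood at 216, 131 and 119.9 CPM in the wells of the control-only library and at 0.0238, 0.134 and 0 CPM in the other control wells. Granulocytes among the picked cells would leave some cells far above the rest, but all 24 cells held Mpo and the highest was 1.55 times the median cell. Elane and Prg2 had medians of 112 and 114 CPM and highest cells of 229 and 194 CPM. Mcpt8 and Ctsg were less even, with medians of 28.5 and 64.6 and highest cells of 202 and 261 CPM, and were found in 12 and 9 of the 55 other control cells, so for them expression by some of the cells stays open. The proportions of the 3 transcripts differed by at most 1.48 percentage points between a well and the pool of that library. For Mpo, Elane and Prg2 these values fit molecules from outside the cells, spread over the library's barcodes, as a candidate source, though the source itself was not identified and granulocytes were the only biological explanation tested.

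Cells of 1 well resembled each other slightly more than cells of other wells of the same library and treatment. Over 126 cells thinned to 50000 molecules, the mean correlation was -0.0140 within and -0.0409 between wells, a difference that 0.001 of 1000 reassignments of cells to wells reached, the smallest share possible. Cells of P1w7 correlated across libraries more than with other wells there, by 0.0545, past the bound written beforehand, and 0.007 of reassignments reached that difference, a condition added afterwards. Within TP24 the 3 pairs of P1w7 cells had a mean of 0.01297, against -0.106 with other wells, whereas the 1 pair in TP25 went the other way, at -0.0406 against -0.02505. The difference across libraries argues against joint handling in 1 library as the whole cause for P1w7, and with 6 pairs of cells from 1 well it excludes nothing for the others. Descent from 1 founder may account for the resemblance, as may the shared culture, which no test separated. For the 2 barcode runs of P1w4 the correlation between runs was -0.00104, under the highest between other wells (0.00184), which met the criterion written beforehand for 2 separate wells; since the correlations within the runs, 0.00183 and -0.00743, lay on both sides of it, the criterion was changed afterwards. The correlation between the runs was above that of either run with any other well (the highest being -0.01175), which goes toward 1 well, but its spread was not tested and 1 pair of other wells lay higher, so whether the runs come from 1 well or 2 cannot be told apart.

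Over 12 genes raised by TGF-β1 and under 0.5 CPM in the control-only library, the level in control cells followed the molecules of the same library's TGF-β1 cells with rank correlations of 0.546 (permutation p = 0.0639) in TP24 and 0.720 (permutation p = 0.0083) in TP25, across genes, which are not independent replicates. Crossing of molecules between barcodes may explain these traces, but with 12 genes and a test redefined after its first values, among them a permutation p added last, it cannot be told apart from low expression. The level in control cells followed the TGF-β1 level of the same library with rank correlations of 0.503 and 0.643 and that of the other library with 0.105 and -0.147, which goes toward crossing, but the difference between these correlations was not tested. The control level summed to 0.687% and 3.88% of the TGF-β1 level.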
